A study of Rattus norvegicus with 8 samples.

How the data were processed

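Total RNA of rat (Sprague-Dawley) myelinating cultures, prepared from embryonic spinal cord per the labels' protocols, was measured on 8 Affymetrix Rat Gene 1.0 ST arrays, 2 for each combination of FGF9 (none, or 100 ng/ml) and time (24 h, 10 days). The deposited table holds 1 value per feature and array on a log2 scale; the scale is read from the values, which ran from about 4 to 15, and is not stated in the labels. Per the submitters' processing notes the authors used Partek 6.5 and GCRMA, a background correction and summarization method for oligonucleotide arrays; further steps and the order of steps are not given in the sources used here. The values were used as deposited, with no further normalization in the reported fits.

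Groups and replicate numbers were taken from the sample titles. Of 29214 features, 15310 had 1 gene symbol in the platform annotation, 323 had several and 13581 had none; only those with 1 were used. Of these, 15279 were found by Entrez identifier in the RefSeq gene table, and 0 symbols changed. For the 527 genes with more than 1 feature the one with the highest mean over the 8 arrays was taken, which left 14506 genes. No genome coordinates are given, because the table names no build.

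Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 1 mean per group, all 8 arrays, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There were 5 contrasts: FGF9 against control at 24 h and at 10 days, the difference of these effects, and 10 days against 24 h in control and in FGF9 cultures. Errors in the text are standard errors of this fit unless the block is named. The same fit with the array name prefix as a fixed block (2 residual degrees of freedom) was planned as an alternative. The labels do not say what the prefix marks. Deviations from the group means of same-numbered arrays, which share a prefix, correlated across genes at 0.757 at 24 h and 0.819 at 10 days; the median residual SD was 0.30 without the block and 0.145 with it.

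The 19 gene lists, written before the data were examined, cover myelin and mature oligodendrocyte, oligodendrocyte precursor, astrocyte, reactive astrocyte, neuron, microglia and macrophage, Schwann cell, endothelial, fibroblast and pericyte, FGF-ERK feedback and target, FGF ligands and receptors, inflammatory cytokine and chemokine, extracellular proteases and their inhibitors, extracellular matrix and proteoglycan, inhibitors of oligodendrocyte differentiation, cholesterol biosynthesis, cell cycle, interferon response and housekeeping genes. Of 363 entries, 322 were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. Some genes are in more than 1 list (Timp1, Gbp2, Fgfr3 and Sox6). The quoted p-values of lists and named genes are adjusted unless called unadjusted.

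Mal, Klk6, genes said to be named after their values were seen, and genes named only through lists added later lie outside the naming rule. The other genes named in the text follow a rule set before the data were examined. For each FGF9 contrast and the control time contrast these were the 10 largest rises and falls among genes that passed with the same sign in both pairs, or, where fewer passed, those that passed filled to 5 by the smallest unadjusted p. The difference took 5 per direction. Added were up to 4 members with the smallest unadjusted p from each list described; and Fgf9, Fgfr1, Fgfr2, Fgfr3, Mbp and Gfap among genes always named. Loci without a standard name and olfactory or vomeronasal receptors were skipped. The rule was also applied to the fit with the block, a choice made after seeing the data. That choice named H19, Fndc3c1, Cbln4 and Fah, among others.

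The fits were tested on data simulated for the 14506 genes from their means, prefix effects and residual spread, with 100 genes changed by 1 log2 unit and 100 by 2 at 10 days. Without the block 0 of 100 genes changed by 1 log2 unit and 0 of 100 changed by 2 were called. With it 86 of 100 and 100 of 100 were called, beside 14 unchanged genes. For lists at 10 days, with the neuron list shifted by 1 log2 unit, camera with the preset correlation called it with no other of the 19, with and without the block, while camera with an estimated correlation did not call it in either fit. Prefix effects in the simulation came from the fit with the block, so it shows what the fits can call if such effects exist. The residual spread was drawn independently for each gene, while real list members can vary together. The simulation therefore does not show how often the preset correlation calls lists that did not move.

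Alternatives planned before the data were examined were the block, leaving out each array, quantile normalization, subtracting array medians, dropping features under the 30th percentile of mean value, testing all features, averaging the features of a gene, moderation with trend and robust settings, no moderation, only the 4 arrays of the groups compared, and other thresholds (unadjusted p under 0.05 with a fold of at least 1.5, and adjusted p under 0.05 with a fold of at least 2). Figures were drawn with matplotlib 3.10.9.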

Results

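Transcript levels were measured in rat spinal cord cultures in which axons become myelinated, kept with or without human fibroblast growth factor 9 (FGF9, a secreted ligand of FGF receptors) at 100 ng/ml. Control and FGF9 cultures were collected after 24 h and after 10 days, with 2 arrays in each of the 4 groups and 8 arrays in all. The titles and cell type labels call every sample a myelinating culture, while the source field names neurosphere-derived astrocytes; the samples are described here by the former. The values are on a log2 scale, and the array medians lay between 6.62 and 6.73. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these arrays, whether technical or biological.

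The arrays carry 3 name prefixes, and the control and FGF9 arrays with the same replicate number at a time share a prefix and form a pair. The prefix is CL1 for pair 1 at 24 h, CL2 for pair 2 at 24 h and for pair 1 at 10 days, and AA1 for pair 2 at 10 days. Pairs differed widely in myelin transcripts before any effect of FGF9. In the 24 h controls, Mal, which encodes a membrane protein of myelin, stood at 11.80 in pair 1 and 7.34 in pair 2. There Klk6, an oligodendrocyte protease, stood at 9.75 and 5.91, and Mbp, myelin basic protein, at 12.67 and 11.06. Mal and Klk6 were named outside the naming rule. The 2 AA1 arrays correlated with each other at r = 0.968 across features and with the 6 other arrays at 0.897 to 0.939, while the 6 others correlated at 0.962 to 0.989. Values with the prefix as a block are therefore given beside those without it wherever they change a call on the effect of FGF9. The log2 difference for FGF9 is identical in the fits with and without this block; only its standard error differs.

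The effect of FGF9 after 24 h was examined as the early response of the cultures. Hbegf, a ligand of the epidermal growth factor receptor, was higher by 2.88 ± 0.46 log2 units (SE, n = 2 per group; 2.71 and 3.04 in the pairs). Clcf1, a cytokine of the interleukin-6 family, was higher by 2.43 ± 0.27, Adamts7, a secreted metalloprotease, by 2.34 ± 0.28, Trib1, a pseudokinase, by 1.83 ± 0.22 and Hectd2 by 1.59 ± 0.25. On the lower side stood Maob, the monoamine oxidase found in astrocytes (-1.64 ± 0.25), Prodh, proline dehydrogenase (-1.57 ± 0.27), Calml4 (-1.25 ± 0.26), Pik3ip1 (-1.18 ± 0.20) and Gstm7 (-0.95 ± 0.20). These 10 genes had the smallest unadjusted p in each direction among genes with the same sign in both pairs, and none passed. Of 14506 genes, 0 passed in limma (smallest adjusted p = 0.718), with 280 at an unadjusted p under 0.05 against 725 expected by chance. A count under 725 is not evidence against an effect, because this fit leaves the differences between pairs in its spread. With the prefix as a block the count was also 0 (smallest adjusted p = 0.122, 1800 genes at an unadjusted p under 0.05). It was 237 when either 10-day pair was left out of that fit, an alternative chosen after seeing the data.

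Among 19 gene lists fixed before the data were examined, camera called 5 at 24 h. The FGF-ERK feedback and target list, genes switched on by FGF receptor signalling through ERK, shifted up by a median of 0.76, with 18 of 19 members higher (adjusted p = 8.07e-18; adjusted p = 0.113 with an estimated correlation). Its members with the smallest p were Ccnd1, cyclin D1 (2.13 ± 0.38), the ERK phosphatases Dusp5 (1.33 ± 0.27) and Dusp4 (0.76 ± 0.23), and Spry4, a feedback inhibitor (1.24 ± 0.43). No member passed over all genes, and 2 passed when adjusted over the list alone (15 with the block). The cell cycle list shifted up by a median of 1.02, with 22 of 23 members higher (adjusted p = 6.68e-11; adjusted p = 0.508 with an estimated correlation), including Mcm5 (1.55 ± 0.63), Bub1 (1.48 ± 0.55), Mcm2 (1.08 ± 0.39) and Tyms (0.58 ± 0.21), which act in DNA replication and mitosis. No member passed over all genes, and 0 passed adjusted over the list alone (18 with the block). This call ended without replicate 2 of the controls (adjusted p = 0.0639) and without replicate 1 of the FGF9 arrays (adjusted p = 0.0618).

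The inflammatory cytokine and chemokine list was called up at 24 h, with a mean of 0.39, a median of 0.17 and 14 of 23 members higher (adjusted p = 0.0149; adjusted p = 0.249 with an estimated correlation). The members with the smallest p were Il11 (2.67 ± 0.60), Ccl2, a chemoattractant of monocytes (2.02 ± 0.97; 0.89 and 3.15 in the pairs), Lif (1.16 ± 0.36) and Il6 (0.37 ± 0.18). The pair medians were -0.01 and 0.33. No member passed over all genes or adjusted over the list alone (1 with the block), and the call ended without replicate 2 of the 24 h controls (adjusted p = 0.12) or of the 24 h FGF9 arrays (adjusted p = 0.115).

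Astrocyte markers shifted down at 24 h, with 15 of 16 members lower, a median of -0.54 and pair medians of -0.40 and -0.76 (adjusted p = 3.45e-12; adjusted p = 0.113 with an estimated correlation). The differences were -1.42 ± 0.38 for S100b, a calcium-binding protein, -1.30 ± 0.42 for the water channel Aqp4, -1.26 ± 0.38 for Gfap, the astrocyte intermediate filament, and -0.70 ± 0.27 for Ndrg2. No member passed over all genes or adjusted over the list alone, and 8 passed as lower over the list alone with the block. Markers of myelin and mature oligodendrocytes also shifted down, with 20 of 21 members lower, a median of -0.48 and pair medians of -0.32 and -0.39 (adjusted p = 0.0166; adjusted p = 0.837 with an estimated correlation). Among them were Aspa (-0.98 ± 0.93), Fa2h (-0.96 ± 1.07), Opalin (-0.73 ± 0.76) and Bcas1 (-0.53 ± 0.35). Mbp differed by -0.33 ± 0.85 without the block and ± 0.17 with it (adjusted p = 0.486 with the block). No myelin gene passed over all genes or adjusted over the list alone (1 lower with the block). The list's median turned to 0.47 without replicate 1 of the 24 h controls and to 0.53 without replicate 2 of the 24 h FGF9 arrays, each of which unbalances the pairs.

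With the prefix as a block, camera called 11 lists at 24 h. Of the 6 added, reactive astrocyte markers (median 0.22, block adjusted p = 0.0456) and extracellular proteases and their inhibitors (0.10, adjusted p = 0.0462) were up. Neuron (-0.22, adjusted p = 0.00491), fibroblast and pericyte (-0.28, adjusted p = 0.0329), inhibitors of oligodendrocyte differentiation (-0.30, adjusted p = 0.0126) and interferon response (-0.42, adjusted p = 0.0456) were down. With the block and an estimated correlation the adjusted p of these 6 lay between 0.398 and 0.689. The interferon genes were lower in pair 1 (median -0.61) more than in pair 2 (-0.05), and Mx2, an antiviral GTPase, differed by -1.45 ± 0.51. Of the remaining lists, oligodendrocyte precursor (median -0.14), microglia and macrophage (-0.12), Schwann cell (-0.18), endothelial (0.14), FGF ligands and receptors (-0.16), extracellular matrix and proteoglycan (0.05), cholesterol biosynthesis (0.08) and housekeeping (-0.02) were not called in either fit.

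**Figure D1:**
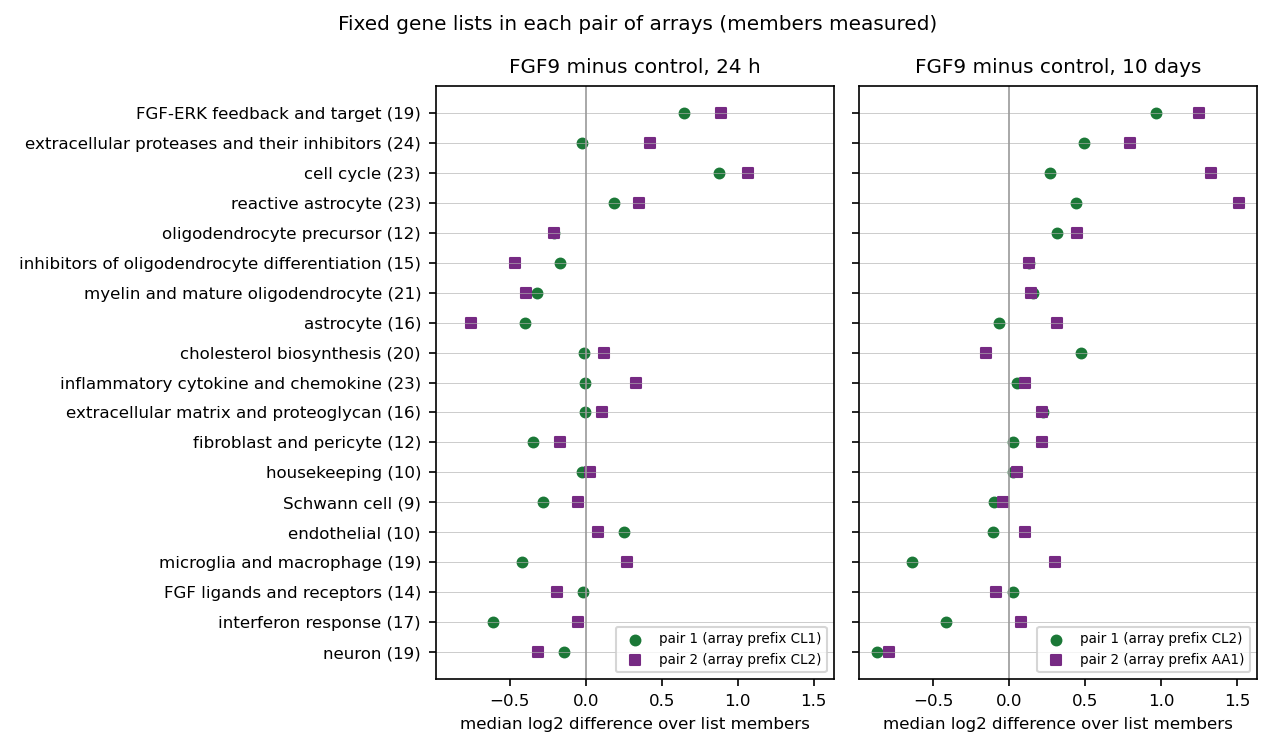
Median log2 difference, FGF9 minus control, over the measured members of each fixed gene list (number in parentheses), at 24 h and at 10 days; circles and squares are the 2 pairs of arrays at each time, with n = 1 control and 1 FGF9 array per point and no error bars. Neuron markers sat at -0.87 and -0.79 in the pairs at 10 days and FGF-ERK targets at 0.97 and 1.25.

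The effect of FGF9 after 10 days was examined as the sustained response. The genes with the smallest p were higher, with Serpina3n, an acute phase protease inhibitor made by reactive astrocytes, higher by 4.22 ± 0.33 log2 units (SE, n = 2 per group). Sectm1b was higher by 3.93 ± 0.34, Lcn2, the iron-siderophore carrier lipocalin 2, by 3.44 ± 0.29, Efhd1 by 2.53 ± 0.22 and Etv4, an ETS factor induced by FGF signalling, by 2.50 ± 0.19. Lower were Lrrc55 (-2.56 ± 0.42), Calml4 (-1.66 ± 0.26), Spaca9 (-1.43 ± 0.21), Sv2b, a synaptic vesicle protein (-1.27 ± 0.24), and Cfap300, a ciliary protein (-1.17 ± 0.22). Without the block 0 of 14506 genes passed in limma (smallest adjusted p = 0.066), with 816 at an unadjusted p under 0.05 against 725 expected by chance. With the prefix as a block 933 genes passed, 453 higher and 480 lower, and all 10 named genes were among them, with an adjusted p between 0.00216 and 0.0284.

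By the naming rule applied to the fit with the block, a choice made after seeing the data, the largest rises were in H19, an imprinted non-coding RNA (4.98 ± 0.55, SE with the block, adjusted p = 0.0173), Serpina3n (4.22 ± 0.24, adjusted p = 0.00595) and Car9, a carbonic anhydrase induced by low oxygen (4.05 ± 0.20, adjusted p = 0.00413). They were followed by Mamdc2 (3.99 ± 0.36), Sectm1b (3.93 ± 0.16), Gfral, the receptor of GDF15 (3.62 ± 0.14), Postn, the matrix protein periostin (3.61 ± 0.23), Adamts1, a secreted protease (3.52 ± 0.30), Lcn2 (3.44 ± 0.27) and Hsd11b1, which regenerates active glucocorticoid (3.19 ± 0.35). The largest falls were in Kcnj13, a potassium channel (-3.00 ± 0.41, adjusted p = 0.022), Olfml1 (-2.88 ± 0.26), Sult1a1, a sulfotransferase (-2.71 ± 0.36), Lix1 (-2.60 ± 0.19) and Lrrc55 (-2.56 ± 0.32). Next came Fmo1 (-2.34 ± 0.43, adjusted p = 0.0372), Omd (-2.32 ± 0.21), Spag6l and Clxn, both of motile cilia (-2.12 ± 0.23 and -2.06 ± 0.20), and the sodium channel Scn7a (-2.02 ± 0.34). Without the block none of these genes passed, and their SEs ran from 0.291 (Lcn2) to 1.575 (Kcnj13). For H19 that SE was 1.01, with differences of 3.72 and 6.24 in the pairs. The count of 933 fell to 151, all of them among the 933, with the prefix as a random block. It ranged from 469 to 1506 when 1 pair was left out of the fit. Control values of Car9 (5.81 and 5.28) and Serpina3n (5.52 and 5.16) lay near the low end of the arrays, whose 5th percentile was 4.79 to 4.89, and such folds can be understated.

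**Figure D2:**
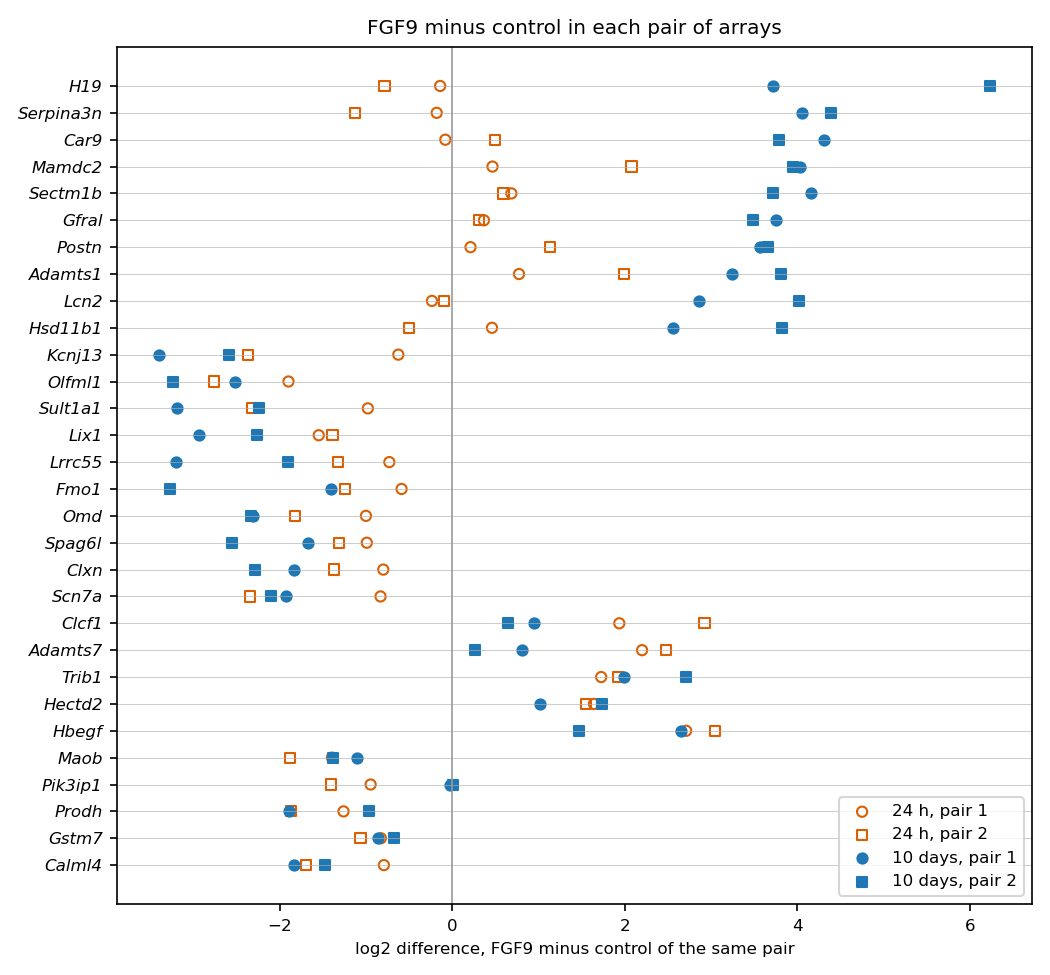
FGF9 minus control (log2) within each pair of arrays for the 20 genes named at 10 days with the block and the 10 named at 24 h; open symbols are 24 h, filled symbols 10 days, circles pair 1 and squares pair 2, each point the difference of 2 arrays with no error bar. Serpina3n differed by 4.06 and 4.38 in the pairs at 10 days and by -0.18 and -1.13 at 24 h.

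Camera called 6 lists at 10 days, and the fit with the block called 6 as well. All 19 measured FGF-ERK feedback and target genes were higher, with a median of 1.12 (adjusted p = 3.99e-19; adjusted p = 0.103 with an estimated correlation; fry adjusted p = 0.0319 without the block and 0.0693 with it). Of these, 0 rose over all genes without the block and 12 with it, and 13 and 17 rose when adjusted over the list alone. Among those that rose with the block were Ccnd1 (2.89 ± 0.38 without the block), Etv4 (2.50 ± 0.19), Etv5 (2.29 ± 0.43) and Fosl1 (1.46 ± 0.31). Reactive astrocyte markers shifted up by a median of 0.69, with 17 of 23 higher (adjusted p = 1.35e-05; adjusted p = 0.642 with an estimated correlation). With the block 6 of them rose, including Serpina3n, Lcn2 and Timp1, a metalloprotease inhibitor (2.24 ± 0.41), and 1 fell, which was complement C3 (-1.95, SE 0.32 with the block, adjusted p = 0.0291; named after its value was seen). Nes, the progenitor filament nestin, differed by 2.14 ± 0.51 (block adjusted p = 0.0552). Adjusted over the list alone, 5 rose and 1 fell (10 and 1 with the block). The pair medians were 0.44 and 1.51, and the call ended without replicate 2 of the 10-day controls (adjusted p = 0.147).

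Extracellular proteases and their inhibitors shifted up by a median of 0.81, with 18 of 24 higher (adjusted p = 0.00117; adjusted p = 0.6 with an estimated correlation). With the block 6 rose and 0 fell over all genes, among them Adamts1 (3.52 ± 0.73), Timp1 (2.24 ± 0.41), Timp4 (1.83 ± 0.42) and Mmp16 (0.89 ± 0.18); both proteases and inhibitors are in this group. Adjusted over the list alone, 4 rose without the block, and 10 rose and 2 fell with it. The cell cycle list shifted up by a median of 0.70, with 19 of 23 higher (adjusted p = 0.00351; adjusted p = 0.948 with an estimated correlation), and pair medians of 0.27 and 1.33. Nusap1 (1.47 ± 0.60) and Tpx2 (1.13 ± 0.68), both of the mitotic spindle, rose with the block, while Rrm2 (1.59 ± 0.87) and Cdk1 (1.21 ± 0.83) did not pass. Adjusted over the list alone 0 passed without the block, and 14 rose and 1 fell with it. Without replicate 2 of the 10-day controls the protease call ended (adjusted p = 0.104), as did the cell cycle call (adjusted p = 0.705), and the latter also ended without replicate 1 of the 10-day FGF9 arrays.

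Neuron markers shifted down at 10 days, with 17 of 19 lower, a median of -0.87 and pair medians of -0.87 and -0.79 (adjusted p = 1.09e-05; adjusted p = 0.659 with an estimated correlation). With the block 13 fell over all genes and 17 adjusted over the list alone (0 and 0 without it). Among them were Nefm, neurofilament medium chain (-1.33 ± 0.70; ± 0.15 with the block), the GABA-synthesising enzymes Gad2 (-1.12 ± 0.60) and Gad1 (-0.84 ± 0.33), and Slc17a6, a vesicular glutamate transporter (-0.93 ± 0.43). The call ended without replicate 2 of the 10-day controls (adjusted p = 0.147) and without replicate 1 of the 10-day FGF9 arrays. Oligodendrocyte precursor markers shifted up by a median of 0.45, with 9 of 12 higher (adjusted p = 0.0109; adjusted p = 0.6 with an estimated correlation). The proteoglycan gene Cspg4 rose with the block (1.70 ± 0.53; ± 0.14 with the block), while Olig1 (1.25 ± 0.40), Gpr17 (0.72 ± 0.28) and Sox10 (0.71 ± 0.31) did not pass over all genes. Adjusted over the list alone 0 passed, and 5 rose with the block. This call ended without replicate 1 of the 10-day controls (adjusted p = 0.216) and without replicate 2 of the 10-day FGF9 arrays (adjusted p = 0.491).

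Myelin transcripts were not lower as a group at 10 days. The list had a median of 0.20 and pair medians of 0.16 and 0.14, with 14 of 21 higher (adjusted p = 0.45). Mbp differed by 0.26 ± 0.85 (0.52 and 0.00 in the pairs, block adjusted p = 0.419). With the block 5 members rose and 0 fell over all genes, and 6 rose and 1 fell adjusted over the list alone. Enpp6 (1.48 ± 0.62; block adjusted p = 0.0325) and Bcas1 (1.37 ± 0.35; block adjusted p = 0.0359), which are switched on in newly forming oligodendrocytes, were among the 5 that rose, while Tf (1.12 ± 0.81) and Opalin (-0.95 ± 0.76) did not pass. Astrocyte markers had a median of 0.15, with pair medians of -0.07 and 0.32 (adjusted p = 0.572), and Gfap differed by -0.18 ± 0.38.

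FGF ligands and receptors moved apart at 10 days, with a median of -0.12, a mean of 0.08 and 7 of 14 higher (adjusted p = 0.921). With the block Fgf2 (1.19 ± 0.30), Fgfrl1 (1.44 ± 0.43) and Fgfr3 (1.29 ± 0.40) rose and Fgf13 (-1.35 ± 0.53) and Fgf9 itself (-1.03 ± 0.48; ± 0.17 with the block, adjusted p = 0.0291) fell. The factor was added as a protein, so its addition brings no Fgf9 transcript. Fgfr1 differed by 0.51 ± 0.25 (block adjusted p = 0.0808) and Fgfr2 by 0.10 ± 0.54. At 24 h Fgf9 differed by -0.22 ± 0.48, Fgfr1 by 0.12 ± 0.25, Fgfr2 by -0.30 ± 0.54 and Fgfr3 by -0.50 ± 0.40, and none passed. The inflammatory cytokine and chemokine list was not called (median 0.13, adjusted p = 0.572); Ccl7, another monocyte chemoattractant, differed by 2.90 ± 1.91 and by 4.43 and 1.38 in the pairs. The lists of fibroblast and pericyte (median 0.04), Schwann cell (-0.04), endothelial (-0.06), microglia and macrophage (-0.09), extracellular matrix and proteoglycan (0.10), inhibitors of oligodendrocyte differentiation (0.22), cholesterol biosynthesis (0.13), interferon response (-0.17) and housekeeping genes (0.01) were also not called. The microglia medians had opposite signs in the pairs, -0.64 and 0.30. Among housekeeping genes, Gusb (0.83 ± 0.16, SE with the block) rose and Hprt1 (-0.72 ± 0.15) fell with the block.

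**Figure D3:**
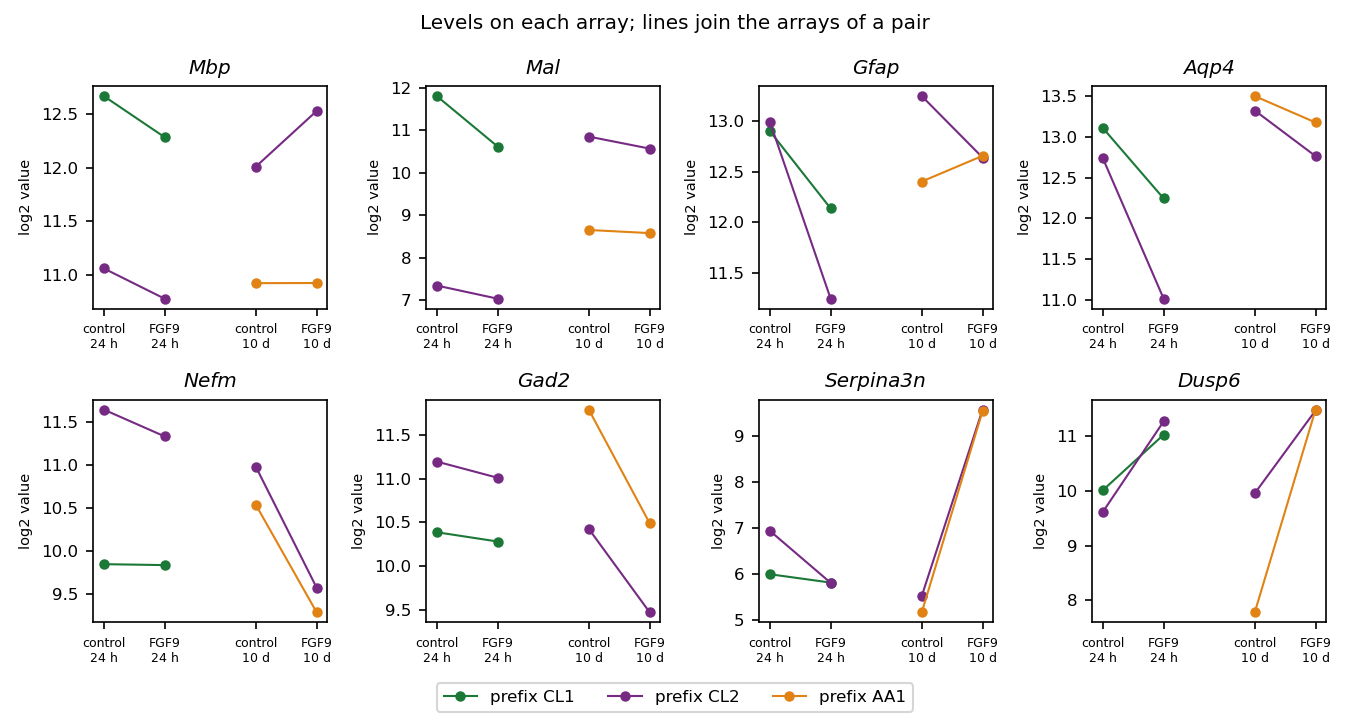
Log2 values on each of the 8 arrays for 8 genes of the myelin, astrocyte, neuron, reactive astrocyte and FGF-ERK lists; each point is 1 array, lines join the control and FGF9 arrays of a pair and colours are the array name prefixes, and the vertical axes differ between panels and do not start at 0. Gad2 fell from 10.43 to 9.47 and from 11.79 to 10.49 in the pairs at 10 days.

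Whether FGF9 acted differently at the 2 times was tested as the difference of its effects, 10 days minus 24 h. The 24 h effect comes from CL1 and CL2 pairs and the 10-day effect from CL2 and AA1 pairs. A difference by time therefore cannot be fully separated from a difference between prefixes in this test. Serpina3n had the smallest p in this test, with a difference of 4.88 ± 0.46 log2 units, followed by Lcn2 (3.61 ± 0.41), Etv4 (2.07 ± 0.26), Sectm1b (3.30 ± 0.47) and Car9 (3.84 ± 0.57). On the lower side stood Spaca9 (-1.62 ± 0.29), Dnajc5b (-1.34 ± 0.27), Adamts7 (-1.80 ± 0.40), Pspc1 (-1.07 ± 0.24) and Clcf1 (-1.63 ± 0.37). None of these 10 passed without the block, where limma called 0 genes (smallest adjusted p = 0.503; 276 at an unadjusted p under 0.05). With the block 7 genes passed, all with a higher effect at 10 days. By the naming rule these are Serpina3n, Car9, Sectm1b, Gfral (3.29 ± 0.20) and Fndc3c1 (3.13 ± 0.26). The other 2 are Gja5, a gap junction protein (2.52 ± 0.18), and Chi3l1, a secreted glycoprotein of reactive astrocytes (3.03 ± 0.25), both named after their values were seen. The 7 became 322 without the 10-day pair 1, and 1 and 0 without the 24 h pairs 1 and 2.

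Camera called 9 lists in the test of the difference, without and with the block. Those with a higher FGF9 effect at 10 days were astrocyte (median difference 0.86, adjusted p = 2.84e-08), oligodendrocyte precursor (0.74, adjusted p = 0.000398), FGF-ERK feedback and target (0.45, adjusted p = 0.000553) and reactive astrocyte (0.46, adjusted p = 0.00258). Fibroblast and pericyte (0.34, adjusted p = 0.00687), myelin and mature oligodendrocyte (0.59, adjusted p = 0.00753), extracellular proteases and their inhibitors (0.19, adjusted p = 0.0234) and inhibitors of oligodendrocyte differentiation (0.49, adjusted p = 0.0402) lists were higher too. The neuron list had a lower effect at 10 days (-0.63, adjusted p = 0.00192). With an estimated correlation 0 lists were called, with an adjusted p between 0.36 and 0.703 for these 9. The astrocyte call remained in each of the 8 fits that left out 1 array. The calls of the oligodendrocyte precursor and FGF-ERK lists each ended without replicate 2 of the 10-day FGF9 arrays (adjusted p = 0.0639 and 0.151), and the others ended in 2 to 7 of those fits. The fibroblast median turned to -0.74 without replicate 2 of the 10-day controls. The myelin median turned to -0.15 without replicate 2 of the 24 h FGF9 arrays and to -0.21 without replicate 1 of the 10-day FGF9 arrays.

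Across the 14506 genes, the log2 effects of FGF9 at 24 h and at 10 days correlated with Pearson r = 0.424 and Spearman rho = 0.34, and 60.4% had the same sign; genes are not independent replicates. The 2 effects share no arrays. Between the pairs of a time the correlation was 0.52 at 24 h and 0.547 at 10 days, and between pairs of different times 0.247 to 0.416. At an unadjusted p under 0.05 without the block, 71 genes were higher at both times against 7.03 for independent lists, and 28 were lower at both against 1.71. With the block these were 363 against 109 and 350 against 106. Both contrasts use the same spread estimate of a gene, so the value for independent lists is only a rough baseline. Leaving out replicate 2 of the 24 h controls lowered r to 0.159, and other arrays lowered it to no less than 0.239.

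The controls at 10 days and 24 h were compared as background to these effects. Car12, a carbonic anhydrase, was higher at 10 days by 2.51 ± 0.33 log2 units, Slc44a3 by 1.63 ± 0.26, Ntsr2, a neurotensin receptor of astrocytes, by 1.32 ± 0.27, Galm by 0.95 ± 0.19 and Mthfs by 0.88 ± 0.18. Actc1, cardiac actin (-1.52 ± 0.24), Rbm14 (-1.09 ± 0.20), Antkmt (-1.01 ± 0.22), Rasa3 (-0.96 ± 0.20) and Etv4 (-0.96 ± 0.19) were lower. None passed, as limma called 0 genes (smallest adjusted p = 0.983; 415 at an unadjusted p under 0.05). Only CL2 arrays cover both times, so the fit with the block rests on 1 CL2 pair at each time for the time difference. It also uses the FGF9 effects, averaged over the pairs of each time. Its residuals hold only differences in the FGF9 effect between pairs, so it does not test time, and its values are given below without p.

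Camera called 7 lists between the control times without the block. Astrocyte markers were higher at 10 days (median 0.20, adjusted p = 0.0352). Lower were cell cycle (-0.87, adjusted p = 3.63e-07), myelin (-0.66, adjusted p = 0.0139), fibroblast and pericyte (-0.74, adjusted p = 0.0286), protease (-0.34, adjusted p = 0.0286), reactive astrocyte (-0.30, adjusted p = 0.0453) and cholesterol biosynthesis (-0.31, adjusted p = 0.0453) lists. With an estimated correlation none was called, with an adjusted p of 0.551 for the 7. In the fit with the block the median was 0.29 for astrocyte and -0.45 for cholesterol biosynthesis genes. There it was 0.722 for myelin, 0.065 for cell cycle, 0.014 for fibroblast and pericyte and -0.011 for reactive astrocyte genes. The direction of the list test turned for each of these, so it depends on the pairs compared. The 24 h controls are CL1 and CL2 arrays and the 10-day controls CL2 and AA1 arrays. The calls without the block therefore mix time with prefix. In FGF9 cultures the same comparison of times gave 0 genes without the block (smallest adjusted p = 0.0784; 1430 at an unadjusted p under 0.05). Astrocyte markers were higher (1.10, adjusted p = 2.92e-09; adjusted p = 0.346 with an estimated correlation) and cell cycle genes lower (-1.05, adjusted p = 2.33e-07; adjusted p = 0.577 with an estimated correlation). In the fit with the block these FGF9 time medians were 1.06 for astrocyte, -0.09 for cell cycle, 1.48 for myelin and -1.29 for neuron genes. Without the block they were -0.03 for myelin and -0.22 for neuron genes.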

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

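The tests of scaling, of dilution, of cell shares and of the pairs below were chosen after the results were seen; the second neuronal list was written down before its values were read.

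The effect of FGF9 differed between 10 days and 24 h by the test of the difference for 9 fixed lists, in log2 units of the median: astrocyte 0.862, oligodendrocyte precursor 0.739, myelin and mature oligodendrocyte 0.593, inhibitors of oligodendrocyte differentiation 0.489, reactive astrocyte 0.457, FGF-ERK feedback and target 0.454, fibroblast and pericyte 0.339, extracellular proteases and their inhibitors 0.188 and neuron -0.631. With an estimated correlation none of the 9 was called, with an adjusted p between 0.36 and 0.703. The array prefixes differ between the times, so time and prefix cannot be fully separated here. With the block 7 genes passed the same test, Serpina3n (4.879), Car9 (3.844), Sectm1b (3.295), Gfral (3.285), Fndc3c1 (3.132), Chi3l1 (3.034) and Gja5 (2.523).

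The first pattern is that 0 genes passed at 10 days without the block and 933 with it. The log2 differences are identical in both fits, so the counts differ only through the estimated spread and its degrees of freedom. The median residual SD was 0.3 without the block and 0.145 with it. The lower of the correlations of deviations of same-numbered arrays was 0.757, so the spread within a group is mostly shared by both arrays of a pair. Differences between the pairs that the FGF9 and control arrays of a pair share enter the residual spread only without the block. Myelin transcripts carried such differences, as with Mal, a gene named outside the naming rule, at 11.80 and 7.34 in the 24 h controls. Whether a prefix marks a culture preparation, a hybridisation or both cannot be read from the labels and stays open.

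The second pattern is the lower level of neuron markers with FGF9 at 10 days. For scaling between arrays, the list's median was -0.878 after quantile normalization, with a housekeeping median of 0.01. The deposited arrays already had nearly equal medians (6.62 to 6.73). Quantile normalization could therefore hardly move the list and is a weak test of scaling. A change limited to the genes of the fixed list is argued against by a second list of 27 measured neuronal genes, whose median was -0.79, with all 27 lower and 23 passing with the block when adjusted over the list alone (0 without it). With an estimated correlation its unadjusted value was 0.203. For dilution of neurons by more of every other cell type alike, 3 of the other 7 cell type lists had medians above 0 in both pairs (myelin, oligodendrocyte precursor, fibroblast and pericyte). None lay below -0.2 in both. Dilution, other ways to a lower share of neurons, which were not tested, and lower expression per neuron therefore cannot be told apart here. An earlier form of that test, which asked how far the other medians spread within a single pair, spoke against dilution through the microglia median of 1 pair; it was replaced after its result was read, because that median was -0.64 in one pair and 0.30 in the other.

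The third pattern is the lower level of astrocyte markers with FGF9 at 24 h and not at 10 days. For scaling between arrays, the list's median was -0.517 after quantile normalization, a weak test here too because the array medians were already nearly equal. Under a lower share of astrocytes in the FGF9 cultures at 24 h the markers of other cells would be higher if those cells took the place of astrocytes, while 5 of the other 7 cell type lists had medians below 0 in both pairs. These medians were small, and dilution by cells outside the lists, such as proliferating progenitors, would lower them too and was not tested. A lower share and a change of expression within astrocytes are therefore both left open. The cell cycle median was 1.02 at the same time.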

How the results depend on the processing

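The random block, the fits without the AA1 arrays and the alternatives to the block were chosen after seeing the data. The replicate block changed the gene counts from 0 to 933 at 10 days, 7 for the difference, 1 for the control times and 1589 for the FGF9 times, and lists at 24 h from 5 to 11; the 24 h gene count stayed at 0. For the times the fit with the block rests on 1 CL2 pair at each time, so those 2 counts do not test time. With the prefix as a random block the counts were 151 at 10 days, 4 for the difference and 209 for the FGF9 times. Lists were not run with it. All 5 gene counts stayed at 0 under quantile normalization, array medians, the dim filter, all features, averaged features and trend and robust moderation, in each fit without 1 array, and at adjusted p under 0.05 with a fold of at least 2; without moderation 1 gene passed at 10 days. The 4 counts that can be fitted on the arrays of 2 groups alone were 0 there too. None of these fits has the block. In the simulation the fit without the block called 0 of 100 genes changed by 2 log2 units at 10 days. The zeros therefore say little about whether genes changed. At an unadjusted p under 0.05 and a fold of at least 1.5 the counts were 213, 707, 276, 330 and 1257, for 24 h, 10 days, the difference, control times and FGF9 times.

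With the block, leaving out either 10-day pair gave 237 genes at 24 h, since the spread then comes from the 24 h pairs alone, and all features gave 1. At 10 days leaving out either 24 h pair gave 469, and leaving out 10-day pair 1 or 2 gave 1506 or 569; for the difference the counts were 1 and 0 without the 24 h pairs 1 and 2, 322 without 10-day pair 1, and 0 with all features. The cause was not tested. Under the scalings 453 rises and 480 falls at 10 days became 471 and 518 (quantile) or 554 and 408 (array medians), which moved the share of rises from 48.6% to 57.6%.

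List counts with an estimated correlation were 0 in the 4 contrasts. With fry they were 0, 1, 0 and 0 at 24 h, 10 days, control times and the difference. With the block fry gave 0, 0, 1 and 1. Both of the latter were the myelin list (fry adjusted p = 0.00882 and 0.00723), the former not a test of time. In the simulation the estimated correlation missed a list shifted by 1 log2 unit. Its genes were drawn independently, so this gives no ground to prefer the preset correlation. The list counts that follow are from camera with the preset correlation. Without the AA1 arrays they were 9 at 24 h and 1 for the control times, and 4 for the control times without dim features. Leaving out single arrays gave 5 to 8 lists at 24 h, 3 to 9 at 10 days, 3 to 7 for the control times and 3 to 10 for the difference, and r between the effects from 0.159 to 0.462. These fits leave a group with 1 array, assumed to vary like the others, and unbalance the pairs.

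Medians of control time lists turned with the replicate block to 0.722 (myelin), -0.011 (reactive astrocyte, whose mean turned up), 0.014 (fibroblast and pericyte) and 0.065 (cell cycle), and without the AA1 arrays to 0.145 (myelin), 0.15 (reactive astrocyte) and 0.176 (fibroblast and pericyte). Without single arrays, the myelin median turned to 0.469 and 0.531 at 24 h (lowest -1.271), 0.333 for the control times (lowest -1.427) and -0.148 and -0.209 for the difference (highest 1.577). Reactive astrocyte turned to 0.15 (lowest -1.148) and fibroblast to 0.176 (lowest -1.805) for the control times, and fibroblast to -0.736 for the difference (highest 2.033). Among genes at 24 h, Mbp turned to 0.471 and 0.42 (lowest -1.136), Fa2h to 0.265 and 0.266 (lowest -2.179), Fgfr2 to 0.226 and 0.323 (lowest -0.925), Fgf9 to 0.322 and 0.312 (lowest -0.769) and Fgfr3 to 0.031 (lowest -1.038). At 10 days Mbp turned to -0.283 and -0.542 (highest 1.063), Fgfr2 to -0.289 (highest 0.48) and Gfap to 0.245 (lowest -0.598). Between control times Cbln4 turned to 0.099 and 0.154 (lowest -1.077) and Fah to -0.086 (highest 1.038). No list or named gene turned under either scaling. The list calls followed over all alternatives are counted by the direction of the list test, not of the median. Of these 296 stayed and 122 ended with the direction kept (27 of these with the estimated correlation and 26 with fry). The other 14 turned, of which all but 1 were also no longer called. The myelin median of -0.209 for the difference is not among the 14, since the direction of the test was kept there. Array values give no background level here, so changes of genes near the low end are limited from below.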

Other observations

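The lists below were written after the data had been seen. The predictions for the members not yet looked at were written before those values were read. The prediction for the interleukin-6 family did not provide for a fall, and its reading was changed from undecided after the value was known. List p-values in this part are adjusted over 5 such lists at 2 times.

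At 10 days genes of the response to low oxygen were higher with FGF9 beyond Car9. Of 27 measured genes of this list 23 were higher, with a median of 0.55 and pair medians of 0.68 and 0.66, and with the block 8 rose over all genes. With an estimated correlation the unadjusted value of the whole list was 0.184. The 27 include 5 genes already looked at, Car9 among them, and 6 of the 8 are from the 22 others, such as the angiogenic factor Vegfa (1.38 ± 0.14, SE with the block), the lactate exporter Slc16a3 (1.74 ± 0.26), hexokinase Hk2 (1.04 ± 0.21) and Egln1, an oxygen-sensing hydroxylase (0.75 ± 0.13). Of 22 measured motile cilia genes 20 were lower, with a median of -0.98 and pair medians of -0.64 and -1.26 (unadjusted value 0.0879 with an estimated correlation). These include Spaca9, Clxn, Spag6l and Cfap300, which prompted the list and are 4 of the 7 that fell with the block. The 3 others are Ccdc39 (-1.25 ± 0.16), Cfap126 (-1.33 ± 0.15) and Zmynd10 (-1.29 ± 0.22). At 24 h the list was lower as well, with a median of -0.39, 20 of 22 lower and no gene passing (camera adjusted p = 4.12e-05; with an estimated correlation the unadjusted value was 0.276).

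A hypoxia response may be part of the 10-day pattern, as a hypothesis. The 22 members not looked at before had a median of 0.545 (camera adjusted p = 0.00017), and with an estimated correlation the unadjusted value was 0.28. Aldoa (-0.02 ± 0.13) and Pgk1 (0.19 ± 0.14), glycolytic genes of the list, did not pass while Hk2 did, and oxygen in the cultures was not measured, so induction of single members by other routes stays open. A fall of motile cilia genes in general is likewise a hypothesis: the 18 members not looked at had a median of -0.735 (camera adjusted p = 1.2e-08), and with an estimated correlation the unadjusted value was 0.122. Foxj1, the factor that drives such genes, differed by -0.59 ± 0.14 (block adjusted p = 0.068). Fewer ciliated cells, such as ependymal cells, and lower expression in them were not separated.

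A STAT3 response is a candidate explanation for the acute phase genes at 10 days. The 20 members not looked at had a median of 0.302 (camera adjusted p = 2e-04), and with an estimated correlation the unadjusted value was 0.0972. They were led by Socs3 (1.85 ± 0.19, SE with the block, adjusted p = 0.0173), a feedback inhibitor of the pathway. Several classical members, such as A2m (-0.14 ± 0.23) and Hp (0.00 ± 0.23), did not pass. At 24 h the same 20 had a median of 0.07 (camera adjusted p = 0.927). Of the interleukin-6 family at 24 h, Clcf1, Il11, Lif and Il6 had differences above 0 in both pairs that did not pass in either fit. With these 4, which prompted the list, the 7 measured members had a median of 0.37 (camera adjusted p = 0.000798; unadjusted value 0.0236 with an estimated correlation). The 3 others, Osm, Ctf1 and Cntf, had a median of -0.557 (camera adjusted p = 0.0139; unadjusted value 0.0593 with an estimated correlation), with Osm at -0.07 and of opposite sign in the pairs. They do not carry a rise of the whole family, which is the reading chosen after their value was known. That reading is weak, because 3 genes are few.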
